A study of Mus musculus with 4 samples.

How the data were processed

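RNA sequencing libraries of primary mouse embryonic fibroblasts were measured, 1 library for each of 4 genotypes: wild type (WT), Zfp871-/-, Trp53-/- and Trp53-/-; Zfp871-/-. Per the labels, the cells were C57BL/6, came from embryos of 12.5 to 13.5 days post-coitum and were harvested while dividing at passage 4. Per the series description, an intercross of double heterozygotes gave WT, Trp53-/- and double-null cells, and an intercross of Zfp871 heterozygotes gave WT and Zfp871-/- cells. Which of the crosses the sequenced WT cells came from, whether embryos were pooled, and how either allele was built are not given in the sources used here.

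The deposited count table holds raw counts per Ensembl gene that the authors made with fastp, STAR and featureCounts on mm10, per the submitters' processing notes. The versions of these tools, the strand setting and the annotation release are not given in the sources used here. Because no strand setting is stated, reads of antisense and overlapping genes could not be separated and such genes are uncertain. The table lists 54532 gene IDs, of which 54495 were found in GENCODE M21 (GRCm38/mm10), the source of symbols, gene types and coordinates. The other 37 IDs took 0.004% to 0.005% of the counts of a library.

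A deposited table per library holds normalized values, whose unit its header does not give. These values were read as FPKM of the authors because each equals the deposited count divided by a fixed length per gene and 1 factor per library. The factors stood at 1, 0.9587, 1.0632 and 1.0591 relative to WT, in the order WT, Zfp871-/-, Trp53-/- and Trp53-/-; Zfp871-/-, and equalled the ratios of the DESeq2 median-of-ratios size factors of the counts. The lengths equalled the GENCODE M21 union exon length within 0.1% for 95.9% of 17633 genes. The FPKM values served only as this check on 17641 genes, and the zeros of both tables fell on the same genes with 0 differences.

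Counts were normalized with the TMM method of edgeR 4.0.16 (R 4.3.3), with factors of 0.978, 0.9438, 1.0406 and 1.041 in the same order. Genes with a CPM (count scaled to library size) of at least 1 in at least 2 of the 4 libraries were kept, which left 13306 genes. Each pair of libraries was compared as the log2 ratio of normalized CPM with a prior count of 2. A gene was counted as higher or lower at a ratio of at least 2-fold. Intervals given for a log2 ratio are exact (Clopper-Pearson) binomial 95% intervals of the ratio of both counts, and many named genes are given without one. The intervals cover counting error only, since reads without molecular identifiers are not independent molecules and no culture was repeated. Where a library had 0 counts, the ratio is a lower bound computed against 3 counts in that library.

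5 pairs were compared: Zfp871-/- with WT, the double null with Trp53-/-, Trp53-/- with WT, the double null with Zfp871-/-, and the double null with WT. The pairs that measure Zfp871 loss share no library with each other, and the same holds for the pairs that measure Trp53 loss. The only test was the edgeR quasi-likelihood test of the additive design Trp53 + Zfp871 with Benjamini-Hochberg adjustment at 0.05. It takes the 4 libraries as 2 per level of each factor, has 1 residual degree of freedom, and counts any difference between backgrounds as error. The common dispersion was 0.0302. In the text, rose and fell are used only for genes past this test.

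The test was checked on simulated counts for the 13306 genes, with 200 genes changed. For Zfp871 loss 58% of genes changed 2-fold and 98% of genes changed 4-fold were recovered, with 10 false calls. For Trp53 loss these shares were 59% and 94%, with 2 false calls. Simulated libraries have no litter or culture differences. All simulated genes also shared the common dispersion, and each change was the same in both backgrounds. These shares therefore do not show how large a difference the test could find in the real counts.

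The median log2 ratio of 33 gene lists was set against 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. The lists cover p53 targets and regulators, cell cycle, senescence, apoptosis, inflammation, interferon response, lipid and glucose metabolism, stress responses, matrix and contractile genes, ribosomal and mitochondrial genes, Hox and imprinted genes, sex, the zinc finger cluster around Zfp871, and markers of other cell types. 4 more lists were written after the main results and before their own values were seen. Genes within 5 Mb of Zfp871 and of Trp53 were examined separately.

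The genes named were chosen by a rule fixed before the data were examined. It takes the 10 genes highest and the 10 lowest in both backgrounds for each loss, ranked by the smaller of both ratios. It adds the 6 most positive and 6 most negative differences between backgrounds of Zfp871 loss, the 5 highest and 5 lowest ratios of the double null to WT, and up to 4 members of each list. At least 50 counts in a library of each pair were required, and predicted genes without an established name were counted but not named. Cdkn1a and Mdm2 were always named. Some genes that the rule selects are not reported here. The alternatives tried were DESeq2 size factors or total counts in place of TMM, 3 other filters on low counts, prior counts of 0.5 and 5, windows of 1 and 20 Mb, random lists without matching, and the p53 list without Cdkn1a and Mdm2. Further alternatives left out the genes near both targets or replaced the test by DESeq2 1.42.0, limma-voom (limma 3.58.1) or robust edgeR dispersions. Thinning to the smallest library and leaving out immune genes were added after the data were seen. Tables were computed with Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.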

Results

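Gene expression was measured by RNA sequencing in primary mouse embryonic fibroblasts (MEFs), the mixed connective-tissue cells that grow out of dissociated embryos. 1 library was made for each of 4 genotypes: WT, Zfp871-/-, Trp53-/-, and Trp53-/-; Zfp871-/- (double null). The libraries held 19303167 counts in WT, 19974054 in Zfp871-/-, 21004078 in Trp53-/- and 22324599 in the double null. Protein-coding genes took 97.7% to 98.6% and mitochondrial genes 1.31% to 1.52% of the counts. No genotype had a replicate library, so the pairwise differences given here have no replicate check and compare libraries rather than conditions. Trp53 encodes p53, a transcription factor that stops the cell cycle and triggers cell death after damage. Mdm2 encodes the ubiquitin ligase that degrades p53 and is itself induced by p53. Zfp871 encodes a zinc finger protein, and the title of the series ties its loss to p53 and Mdm2.

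The targeted genes were lower in the libraries labelled null for them. Zfp871 (ENSMUSG00000024298, chromosome 17, 32765496 to 32788287, GRCm38/mm10) had 660 counts in WT, 327 in Zfp871-/-, 784 in Trp53-/- and 307 in the double null. The log2 ratio of Zfp871 loss was -1.01 (95% interval -1.21 to -0.82) with Trp53 and -1.43 (-1.64 to -1.25) without it. Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873) had 2383, 2413, 1233 and 1382 counts in the same order. The log2 ratio of Trp53 loss was -1.16 (-1.26 to -1.06) with Zfp871 and -1.10 (-1.20 to -1.01) without it. RNA counted to a null gene does not show protein, and counts per gene do not show which exons were lost. Trp53 RNA did not differ beyond counting error between Zfp871-/- and WT, with a log2 ratio of 0.02 (-0.06 to 0.10).

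**Figure D1:**
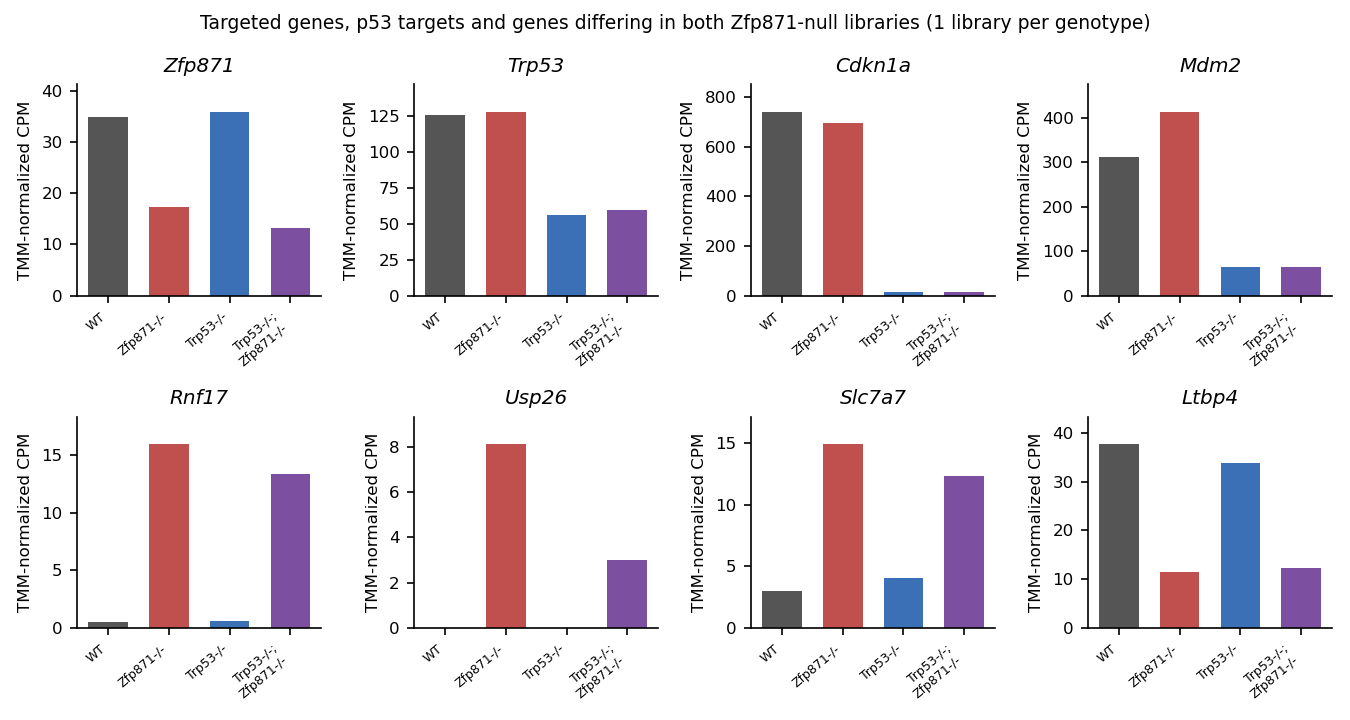
TMM-normalized CPM of 8 genes in each of the 4 libraries, 1 bar per library. Zfp871 and Trp53 are lower in the libraries labelled null for them, Cdkn1a and Mdm2 are low in both Trp53-null libraries, and Rnf17, Usp26, Slc7a7 and Ltbp4 differ in both Zfp871-null libraries.

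Zfp871 loss was first read on the p53-Mdm2 axis. Cdkn1a, the p53 target that inhibits cyclin-dependent kinases, had almost the same level in Zfp871-/- as in WT. Mdm2 was higher in Zfp871-/- than in WT where Trp53 was intact and did not differ beyond counting error where Trp53 was lost. Perp and Sesn1, p53 targets that act in apoptosis and in the response to oxidative stress, were lower in Zfp871-/- than in WT, while other targets lay on either side. Cdkn1a had 13979 counts in WT and 13103 in Zfp871-/-, a log2 ratio of -0.09 (-0.13 to -0.06), and 341 counts in each of the Trp53-null libraries. Mdm2 had 5875 counts in WT and 7786 in Zfp871-/-, a log2 ratio of 0.41 (0.36 to 0.46). It had 1397 and 1523 counts in Trp53-/- and the double null, a log2 ratio of 0.04 (-0.07 to 0.14). The median log2 ratio of 44 p53 targets was -0.12 with Trp53, where 15 were positive and 3.24% of matched random lists lay below it, and 0.01 without Trp53. The median difference between both backgrounds was -0.14, with 1.47% of random lists below it, and without a filter on low counts it was -0.137 and no longer stood apart from random lists. Of targets with at least 50 counts in WT or Zfp871-/-, Perp (-1.26), Sesn1 (-1.01), Cgref1 (-0.95) and Dcxr (-0.86) had the lowest log2 ratios. In all, 3 of the 44 targets were at least 2-fold lower in Zfp871-/- than in WT. The regulators of p53 had medians of 0.12 and 0.07, and the apoptosis genes 0.12 and 0.04. Single regulators could differ more, since Cdkn2a, which restrains Mdm2 through p19Arf, was lower in Zfp871-/- than in WT. It was higher in the double null than in Trp53-/-. Counts per gene do not show which transcripts of Cdkn2a differed.

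Cell division genes were higher in Zfp871-/- cells than in WT, and the shift was smaller where Trp53 was lost. Under TMM scaling each of the 35 mitotic genes, among them Cenpe, Tpx2, Ncapg and Aurka, which build and separate the spindle, was higher in Zfp871-/- than in WT. Replication genes such as Pola1 and Mcm10, which start DNA synthesis, lay in the same direction. Genes of glycolysis and of cholesterol synthesis were for the most part also higher in Zfp871-/- than in WT. The mitotic list had a median log2 ratio of 0.51 with Trp53 and 0.13 without it, and no member reached 2-fold. Markers of another tissue differed in the same pair, since the chondrocyte and bone list had a median of -0.61 in Zfp871-/- against WT. The replication list had medians of 0.53 and 0.12. The glycolysis list had medians of 0.36 and 0.17. The cholesterol list had a median of 0.35 with Trp53, where 20 of 23 genes were higher, and of -0.25 without it, where 22 were lower. Interferon-stimulated genes had a median of 0.17 with Trp53 and of -0.48 without it, where all 30 were lower in the double null than in Trp53-/-. Macrophage markers moved with them, with medians of 0.29 with Trp53 and -0.29 without it, where 13 of 15 were lower. A second macrophage list of 34 genes had medians of 0.00 with Trp53 and -0.30 without it, where 29 were lower. The higher median with Trp53 was thus seen in the first list only.

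Few genes were at least 2-fold apart in the same direction after Zfp871 loss in both backgrounds. Rnf17 and Usp26, which are best known from male germ cells, were almost silent where Zfp871 was present. Slc7a7, a transporter of cationic amino acids, and B3gnt5, a glycolipid-forming glycosyltransferase, were higher in both Zfp871-null libraries. Ltbp4, which binds latent TGF-beta to elastic fibres, Ccn3, a matrix signalling protein, and Nt5e, an ectoenzyme that makes adenosine, were lower in both. Rnf17 (ENSMUSG00000000365, chromosome 14, 56402581 to 56525032) had 10 counts in WT, 301 in Zfp871-/-, 14 in Trp53-/- and 311 in the double null, log2 ratios of 4.68 (4.01 to 5.99) and 4.19 (3.62 to 5.27). Usp26 (ENSMUSG00000055780, chromosome X, 51753959 to 51801233) had 0 counts in both libraries with Zfp871, 153 in Zfp871-/- and 70 in the double null, at least 51.1-fold and at least 21.9-fold higher. Slc7a7 had log2 ratios of 2.27 (1.89 to 2.74) and 1.59 (1.27 to 1.98). Ltbp4 (ENSMUSG00000040488, chromosome 7, 27305136 to 27337692) had 711, 215, 737 and 287 counts, log2 ratios of -1.72 (-1.95 to -1.50) and -1.44 (-1.65 to -1.25). Ccn3 had log2 ratios of -1.04 and -1.06, and Nt5e of -2.28 and -1.06. The other genes named as higher in both backgrounds were B3gnt5, Gap43, Sp7, Lrrtm2, Neb and Vat1l, with log2 ratios between 0.81 and 1.53. Those named as lower were Enpp2, Wscd2, Fam180a, Clu, Rerg and the pseudogene Serpina3h, whose reads are uncertain because it belongs to a family of near-identical genes. Their log2 ratios lay between -3.43 and -0.97. Several genes lower in both backgrounds were also lower in Trp53-/- than in WT, where Zfp871 was intact. The log2 ratios there were -2.58 for Enpp2, -2.0 for Wscd2, -1.75 for Nt5e, -1.55 for Clu, -1.14 for Fam180a and -0.92 for Ccn3. Ltbp4 (-0.16), Serpina3h (-0.11) and Rerg (0.19) differed little in that pair.

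Zfp871 loss met few of the same genes in both backgrounds. Of the 13306 genes, 469 were at least 2-fold higher and 529 at least 2-fold lower in Zfp871-/- than in WT (7.5% of genes). In the double null against Trp53-/- these counts were 109 and 134 (1.8% of genes). Counting intervals excluded an equal level for 949 of the first 998 genes and for 222 of the second 243. 35 genes were 2-fold in the same direction in both backgrounds, 14 higher and 21 lower, where independent lists of these sizes would share 9.2. 49 genes were 2-fold in opposite directions, where 9.1 would be shared. Across genes, which are not independent replicates, the correlation of the log2 ratios was 0.03 (Pearson) and 0.07 (Spearman). The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes that rose and 0 that fell with Zfp871 loss over both backgrounds, with a smallest adjusted p of 0.85. In that test 510 genes (3.8%) had an unadjusted p under 0.05. Rnf17, with log2 ratios of 4.68 and 4.19, was not called, so 0 calls do not show that large differences were absent. Without a filter on low counts the same test called 2 genes upward and 4 downward. Adjusted over the list alone, 1 gene was lower with Zfp871 loss in each of 3 lists, the targeted genes, the zinc finger cluster and the chondrocyte and bone genes, and 0 were called in the other lists. Zfp871 itself belongs to both the targeted genes and the zinc finger cluster, so the calls in these lists cannot be read as separate changes. DESeq2's Wald test with the same design called 3 genes that were higher and 5 that were lower, and limma-voom called 0. The DESeq2 calls were Rnf17, Slc7a7 and the predicted gene Gm26917 in one direction and Ltbp4, Lum, Ccn3, Stk26 and Sox6 in the other. Of these, Lum, Stk26, Sox6 and Gm26917 were named after their values were seen.

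**Figure D2:**
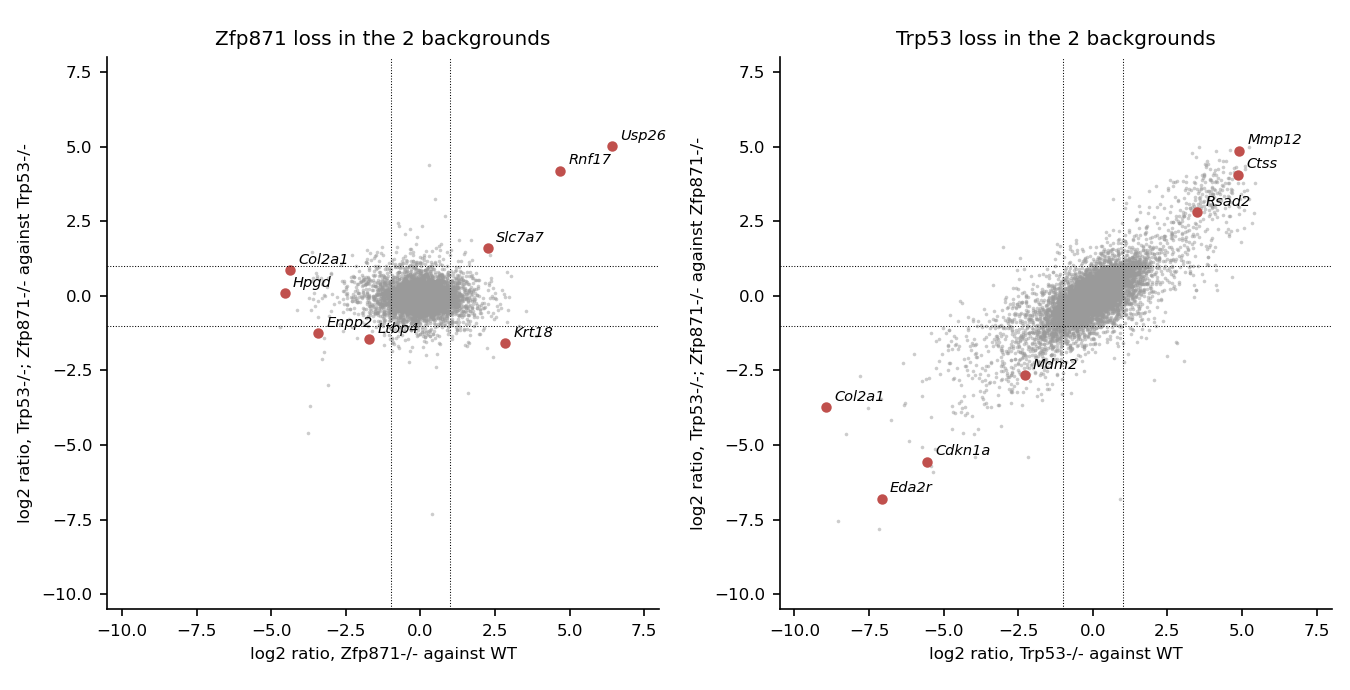
Log2 ratio of each of 13306 genes (grey points) after Zfp871 loss (left) and Trp53 loss (right), with the background that keeps the other gene on the horizontal axis and the null background on the vertical axis; dotted lines mark 2-fold. Trp53 ratios follow each other (Pearson 0.79 across genes) and Zfp871 ratios do not (0.03), apart from genes such as Rnf17, Usp26, Slc7a7 and Ltbp4.

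The genes whose Zfp871 difference changed most with the background included genes of cartilage and epithelium. Col2a1 and Acan, which build cartilage matrix, and Penk, Abi3bp, Hpgd and Cxcl1 were far lower in Zfp871-/- than in WT, and between 0.09 and 0.86 higher on the log2 scale in the double null than in Trp53-/-, where the intervals of Hpgd and Penk included 0. The keratin gene Krt18 and the mesothelial gene Upk3b went the other way. Hoxd13, Hoxd11 and Hoxd10, which pattern the distal limb, were lower in Zfp871-/- than in WT, whereas Hoxc4 was higher. Col2a1 (chromosome 15, 97975602 to 98004695) had 11633 counts in WT, 558 in Zfp871-/-, 25 in Trp53-/- and 50 in the double null, log2 ratios of -4.38 (-4.50 to -4.26) and 0.86 (0.19 to 1.67). Acan had log2 ratios of -3.51 and 0.75, Penk of -3.25 and 0.49, Abi3bp of -3.33 and 0.60, Hpgd of -4.55 and 0.09, and Cxcl1 of -3.11 and 0.61. Krt18 had 9, 75, 86 and 29 counts, Tfpi2 37, 295, 470 and 357, and Rgs7bp 3, 54, 140 and 105. The log2 ratios of Rgs7bp were 3.53 (2.55 to 6.49) and -0.49. The chondrocyte and bone list (9 genes) had medians of -0.61 with Trp53 and 0.39 without it. The Hox list (31 genes) had medians of 1.05 and -0.14, with 16 genes at least 2-fold higher and 6 at least 2-fold lower in Zfp871-/- than in WT. WT stood apart from the other libraries in this list, whose median was 1.20 in Trp53-/- and 1.05 in the double null against WT, but 0.17 in the double null against Zfp871-/-. None of these differences between backgrounds was tested.

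Known targets of p53 fell with Trp53 loss. Among them were Cdkn1a, Mdm2, Eda2r, which encodes a death receptor, and Trp53inp1, a regulator of the stress response. The death genes Pmaip1, Bbc3 and Bax and the survival gene Bcl2l1 fell too. Cdkn2a, whose p19Arf protein restrains Mdm2, rose, but counts per gene do not show which of its transcripts did. Cdkn1a (chromosome 17, 29090976 to 29100727) fell by 5.57 on the log2 scale in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment (SE 0.132, adjusted p 0.00539), with pairwise log2 ratios of -5.56 in each background. Mdm2 (chromosome 10, 117688875 to 117710758) fell by 2.47 in the same edgeR quasi-likelihood test (SE 0.145, Benjamini-Hochberg adjusted p 0.0102), with log2 ratios of -2.28 with Zfp871 and -2.65 without it. Eda2r fell by 7.06 in that edgeR quasi-likelihood test (SE 0.166, Benjamini-Hochberg adjusted p 0.00539). Of 44 p53 targets 30 fell and 1, Casp1, rose, and adjusted over the list alone 37 fell and 1 rose. The list had a median log2 ratio of -1.87 with Zfp871 and -1.53 without it. Cdkn2a had 1042, 547, 3652 and 4722 counts and rose by 2.20 in the edgeR quasi-likelihood test (SE 0.324, Benjamini-Hochberg adjusted p 0.0351). Of the 20 apoptosis genes 5 fell and Birc5 rose, and adjusted over the list alone 5 fell and 2 rose. Inka2, Ano3, Ddit4l and Mab21l3 were also among the genes with the lowest ratios in both backgrounds, with 2 to 20 counts in the Trp53-null libraries. Inka2 had 1313, 1089, 2 and 5 counts, log2 ratios of -8.53 (-12.62 to -7.71) and -7.54 (-9.69 to -6.84). Olfr1318 and Klhdc7a had 0 counts in both Trp53-null libraries, at least 36.7-fold and at least 49.8-fold lower in Trp53-/- than in WT.

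Cell division genes rose with Trp53 loss, and so did genes of macrophages and of the interferon response. The macrophage genes Ctss, C1qb, C1qc, Fcer1g and Tyrobp, which encode a lysosomal protease, complement components and adaptors of immune receptors, rose. The interferon-stimulated genes Oas2, Rsad2 and Gbp3, which act against viruses and other microbes, rose as well. The matrix genes Eln and Lum, which encode elastin and lumican, fell. Of 35 mitotic genes 22 rose (34 adjusted over the list alone), with medians of 1.14 with Zfp871 and 0.78 without it. Of 35 replication genes 25 rose (35 adjusted over the list alone), with medians of 1.24 and 0.83. Of 15 macrophage genes 15 rose (15 adjusted over the list alone), with medians of 4.10 and 3.50. Ctss had 54, 83, 1888 and 1742 counts, and the lysozyme gene Lyz2, chosen after its values were seen, 672, 695, 9136 and 9700. In WT, 14 of the 15 macrophage genes had at least 1 CPM. Of 30 interferon-stimulated genes 23 rose (30 adjusted over the list alone), with medians of 2.40 and 1.85. Of 36 matrix genes 8 fell and 0 rose (17 and 2 adjusted over the list alone), with medians of -0.54 and -0.65. Most cartilage and limb genes were lower in the same pairs. The chondrocyte and bone list had medians of -1.77 and -0.30, and a second list of 26 limb and cartilage genes had -1.03 and -0.81, of which 5 fell (14 adjusted over the list alone). The macrophage elastase gene Mmp12 had 34, 44, 1243 and 1640 counts, log2 ratios of 4.91 (4.49 to 5.52) and 4.86 (4.49 to 5.38). The other genes named as highest in both backgrounds, Cd52, Lilr4b, Ccl3, Fcgr2b, Cd300lb, Clec4a2, Themis2, Fcgr3 and Ms4a6d, are all expressed in leukocytes. Cd52 had 3, 2, 207 and 148 counts, with intervals of the log2 ratio of 4.33 to 8.19 and 4.03 to 8.97.

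**Figure D3:**
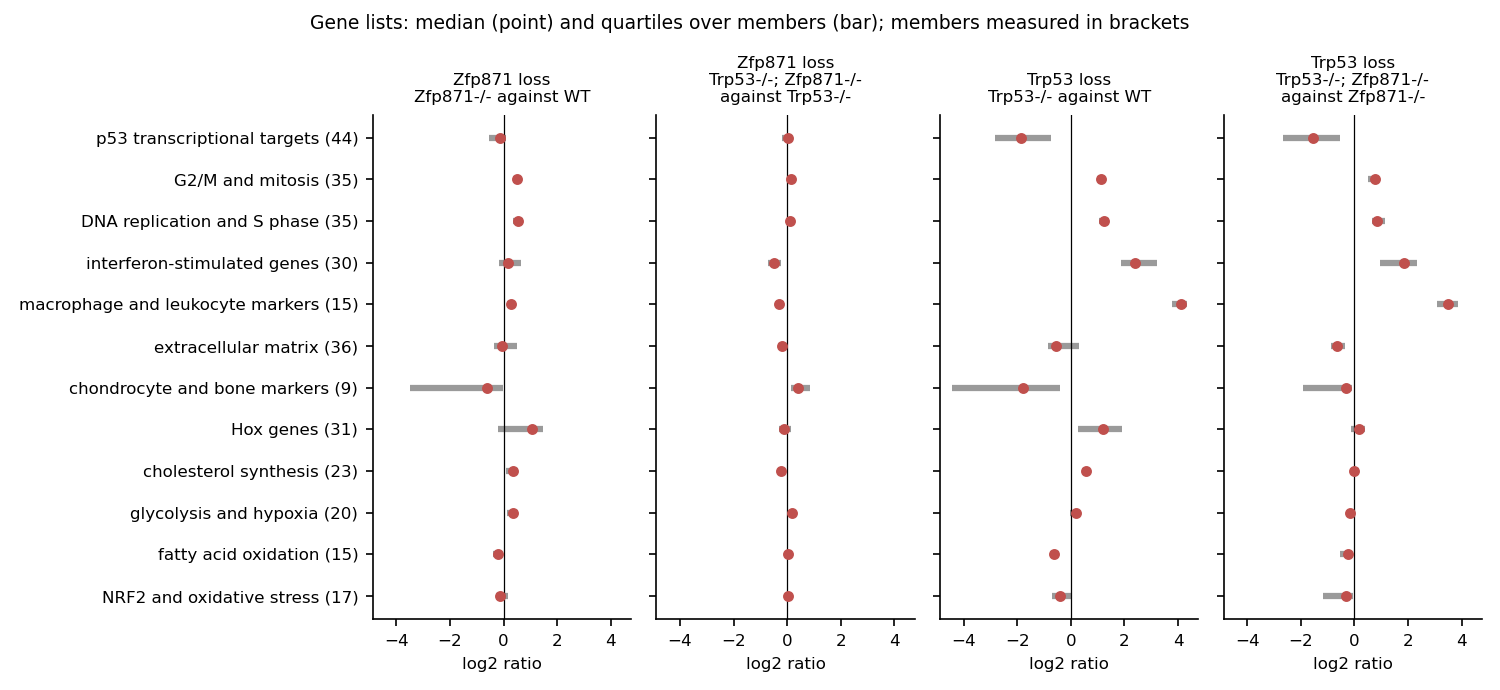
Median log2 ratio (points) and quartiles over members (bars) of 12 gene lists in the 4 pairs that measure Zfp871 loss and Trp53 loss. The p53 targets lie at -1.87 and -1.53 after Trp53 loss and at -0.12 and 0.01 after Zfp871 loss.

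Trp53 loss met largely the same genes in both Zfp871 backgrounds. 1184 genes were at least 2-fold higher and 1181 at least 2-fold lower in Trp53-/- than in WT, and 733 and 842 in the double null against Zfp871-/-. Of these, 1176 genes were 2-fold in the same direction in both backgrounds, 566 higher and 610 lower, where independent lists would share 140. 25 genes were 2-fold in opposite directions, where 140 would be shared. Across genes the correlation was 0.79 (Pearson) and 0.66 (Spearman). The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 667 genes that rose and 574 that fell, with a smallest adjusted p of 0.0054. This test takes libraries of different genotypes as replicates, so its p-values describe these 4 cultures. Per the series description, both Trp53-null genotypes came from the same intercross and Zfp871-/- cells from another, while the cross of the sequenced WT cells is not given. Differences of cross or litter shared by both Trp53-null libraries therefore cannot be told apart from Trp53 loss. With total counts in place of TMM, 867 rose and 423 fell, so that 67.2% of the calls were upward instead of 53.7%. The same scaling gave 938 higher and 694 lower genes in the double null against Zfp871-/- (57.5% higher, 46.5% with TMM) and moved the median of all genes there by 0.14. List medians within 0.14 of 0 in that pair are therefore given without a direction.

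The genes furthest apart between the double null and WT included genes of cartilage, limb and leukocytes. Col10a1, the collagen of hypertrophic cartilage, Col2a1 and Hoxd13 had the lowest ratios to WT together with Inka2 and Ano3, and Mmp9, Mmp12, Themis2, Usp26 and Cd300lf had the highest. Col10a1 (chromosome 10, 34389981 to 34397085) had 4863, 183, 16 and 7 counts, a log2 ratio of -9.34 (-11.06 to -8.70) between the double null and WT. Hoxd13 (chromosome 2, 74668310 to 74671599) had 1904, 142, 14 and 14 counts, a log2 ratio of -7.17. Mmp9, which encodes gelatinase B, had 39, 291, 1893 and 1940 counts, a log2 ratio of 5.27. Cd300lf was at least 17.9-fold higher than in WT, and Usp26 had 0 counts in WT and 70 in the double null. In all, 1169 genes were at least 2-fold higher and 1228 at least 2-fold lower than in WT. The macrophage list had a median of 3.90, the interferon list of 2.03, the p53 target list of -1.90, the chondrocyte and bone list of -1.39 and the mitotic list of 1.26.

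**Figure D4:**
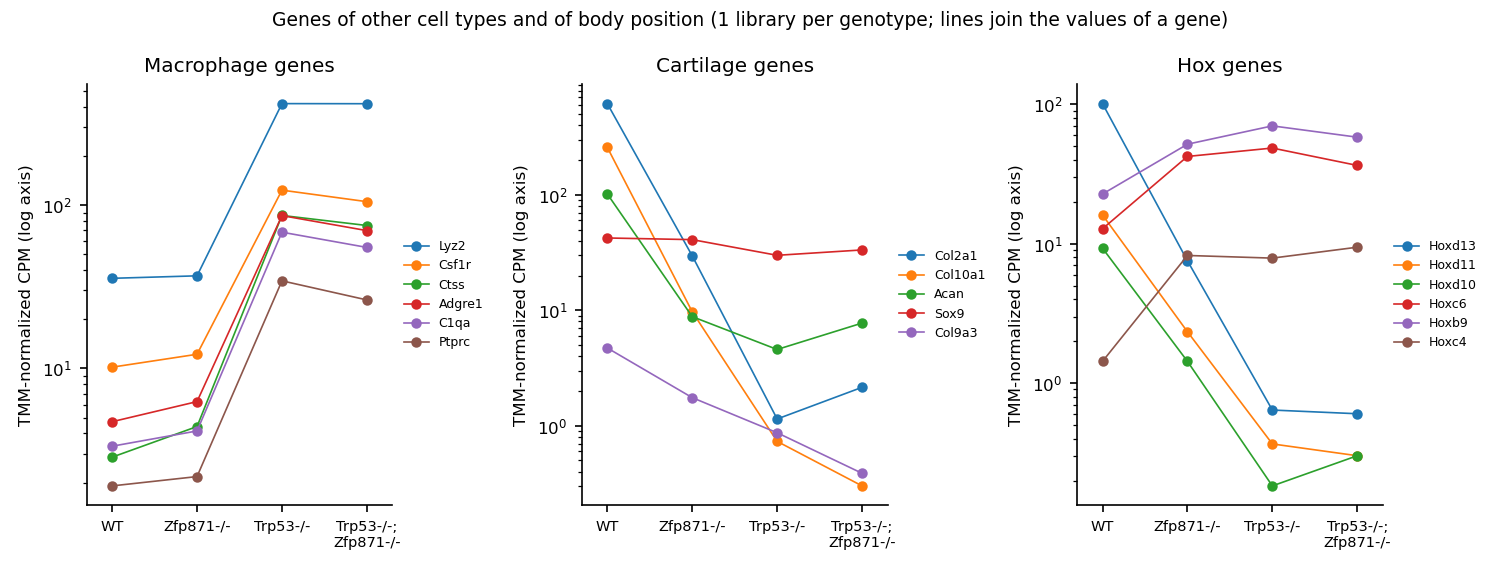
TMM-normalized CPM on a log axis of macrophage, cartilage and Hox genes in the 4 libraries; lines join the values of a gene. The macrophage genes are high in both Trp53-null libraries, and Col2a1, Col10a1 and Hoxd13 are highest in WT; Lyz2, Csf1r, C1qa, Hoxc6 and Hoxb9 were picked after their values were seen.

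Fatty liver disease, named in the series title, involves lipid genes. Of 21 genes of fatty acid synthesis and lipid storage, Cd36, a fatty acid transporter, rose with Trp53 loss, 1 fell, and the same counts were called adjusted over the list alone. Cd36 is also expressed in macrophages, whose 15 listed genes all rose with Trp53 loss. The Zfp871 medians of this list were 0.07 with Trp53 and -0.03 without it. The fatty acid oxidation list (15 genes) had Zfp871 medians of -0.20 and 0.03 and Trp53 medians of -0.63 and -0.24. In it 1 gene rose and 3 fell with Trp53 loss (1 and 6 adjusted over the list alone). In Trp53-/- against WT, 14 of the 15 oxidation genes were lower and all 23 cholesterol genes were higher, with a cholesterol median of 0.55, against -0.01 in the double null compared with Zfp871-/-. No cholesterol gene was called for Trp53 loss, and 0 were called adjusted over the list alone. Plin4, a lipid droplet gene, and Pparg, a fat cell regulator, had log2 ratios of -3.57 and -1.51 in Zfp871-/- against WT, and of 0.10 and -0.46 in the double null against Trp53-/-.

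Genes beside the targets did not stand out from all genes in how often they differed, since the exact interval of each share included the share of all genes. These intervals take neighbouring genes as independent and do not cover the spread between cultures. Within 5 Mb of Zfp871 lay 179 measured genes, of which 7 (3.9%, exact 95% interval 1.6 to 7.9) were at least 2-fold different with Trp53 and 2 (1.1%, 0.1 to 4.0) without it. Within 5 Mb of Trp53 lay 110 genes, of which 23 (20.9%, 13.7 to 29.7) and 16 (14.5%, 8.5 to 22.5) differed after Trp53 loss. Of all genes, 7.5% and 1.8% differed after Zfp871 loss and 17.8% and 11.8% after Trp53 loss. The zinc finger genes of the cluster around Zfp871 (18 measured) had Zfp871 medians of 0.16 and -0.02, of which the former turned to -0.282 among genes of at least 10 CPM in at least 2 libraries. Zfp871 itself was the member with the largest difference.

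The medians of the remaining lists follow for Zfp871 loss with and without Trp53. They were 0.13 and 0.08 for cell cycle inhibitors and senescence, 0.00 and -0.11 for inflammatory genes, -0.06 and -0.21 for matrix genes, and 0.13 and 0.26 for contractile genes, of which 17 of 19 were higher in the double null than in Trp53-/-. They were -0.12 and 0.04 for NRF2 targets, -0.14 and -0.09 for the integrated stress response, 0.32 and 0.12 for immediate early genes, -0.07 and 0.10 for ribosomal proteins, and -0.12 and -0.03 for mitochondrially encoded genes. Imprinted genes had medians of 0.09 and -0.07, muscle genes (6 measured) of 0.32 and 0.48, neural genes (7) of 0.64 and -0.04, fat cell genes (4) of 0.31 and -0.41, and epithelial genes (3) of 2.83 and -1.36. All 3 epithelial genes were at least 2-fold higher in Zfp871-/- than in WT. The 4 endothelial genes had medians of -0.01 and 0.61, the latter 0.35 with the gene at 0 counts set to its bound. None of the 9 listed erythroid genes and none of the 4 listed Y-linked genes passed the filter. With Trp53 loss, 3 inflammatory genes rose and 3 fell (10 and 3 adjusted over the list alone), and 1 NRF2 target rose and 4 fell (1 and 5). Of the Hox genes 2 fell (2 adjusted over the list alone), and of the chondrocyte and bone genes 2 fell (4 adjusted over the list alone).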

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

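In this part, the tests at 10 CPM, of embryo sex, of litters and of the chromosome of Rnf17 and Usp26 were chosen only after the results were seen.

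Some effects pointed in opposite directions in the compared backgrounds, which was not tested, because each genotype had 1 library. 49 genes were at least 2-fold apart in opposite directions after Zfp871 loss with and without Trp53, and 25 genes after Trp53 loss with and without Zfp871. Among the named genes, the difference of the log2 ratios of Zfp871 loss was 4.41 for Krt18, 3.29 for Gvin1, 3.25 for Myrf and 3.21 for Upk3b. Krt18, Upk3b and Myrf had 9, 16 and 46 counts in WT and 29, 23 and 48 in the double null, and both single nulls were above these counts. Gvin1 had 14 counts in WT and 62, 201 and 87 in Zfp871-/-, Trp53-/- and the double null.

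Zfp871 loss gave 998 genes at least 2-fold apart with Trp53 and 243 without it, a ratio of 4.11. WT also stood further from both Trp53-null libraries than Zfp871-/- did. From Trp53-/-, 2365 genes were at least 2-fold apart in WT and 1642 in Zfp871-/-, and from the double null 2397 and 1575. With 1 WT library, these counts cannot separate an unusual WT culture from an effect of Zfp871 that depends on the background. Depth and counting noise are argued against: the ratio was 4.15 with libraries thinned to the smallest total, and 10.65 (330 against 31 genes) among genes of at least 10 CPM in at least 2 libraries. Embryo sex is argued against as well, since the 4 listed Y-linked genes together had at most 1 count in a library and Xist was expressed in all 4; the predicted gene Gm47283, annotated on Y, had 154, 202, 337 and 0 counts in WT, Zfp871-/-, Trp53-/- and the double null, so it separates the double null from Trp53-/-, where differences were fewer, but not Zfp871-/- from WT, and it does not follow the 4 Y-linked genes. For cartilage and limb genes, more limb tissue in the WT culture cannot be told apart from an effect of Zfp871. A second list of 26 measured genes had a median log2 ratio of -0.43 in Zfp871-/- against WT, between the values set for either outcome. In it 9 genes were at least 2-fold lower and 1 higher, and 0.02% of matched random lists lay below the median. The same list had a median of -1.03 in Trp53-/- against WT, where Zfp871 was intact. In the double null against Trp53-/- its median was -0.06. Levels below those of WT were thus not particular to Zfp871 loss in this list. Different litters or crosses may also contribute and cannot be told apart from genotype, since there was 1 library per genotype, Trp53-/- and double-null cells came from one intercross and Zfp871-/- cells from another, and a dependence of Zfp871's effect on p53 stays open as untested.

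Macrophage markers were higher in both Trp53-null libraries. An admixture of lymphoid and erythroid cells is argued against, because 26 genes of these cells together had at most 68 counts in a library. The counts were 25, 31, 51 and 68 in WT, Zfp871-/-, Trp53-/- and the double null. Other blood cells were not covered by this list. Macrophages within the Trp53-null cultures are a candidate source: of a second list of 34 macrophage genes, none in an earlier list, 88.2% (30 genes) were at least 4-fold higher in both, and Lyz2 reached 9136 and 9700 counts. The WT culture held such RNA too, with 19 of these 34 genes and 14 of the 15 first-list genes at 1 CPM or more. Whether Trp53 loss lets macrophages persist, or these cultures began with more of them, was not tested, and no sort that would remove them is described.

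Rnf17 and Usp26 were higher in both Zfp871-null libraries. A direct effect of DNA carried along with the targeted allele on genes beside it is argued against, because 0 of these genes lie on the chromosome of Zfp871. The position of the genes does not decide whether a changed gene near Zfp871 acted on other chromosomes. A general activation of germline genes is argued against, because 0.0% of 14 other germline genes with at least 10 counts were at least 4-fold higher in both libraries. Transcription of a wider region is argued against only for the 6 measured genes within 250 kb of Rnf17 or Usp26, of which 0.0% were at least 2-fold higher in both. These genes were pooled over both regions and genes below the filter were not covered, so the test does not decide the question for each region. The loss of Zfp871 itself, a changed gene near it that acts on other chromosomes, and an unlinked variant that segregated with the allele stay open. None of these was tested.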

How the results depend on the processing

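In this part, thinning to the smallest library and leaving out immune genes were chosen after the data were seen. Of 329 alternative values of the 42 leading results, 268 kept their direction and size or call, 60 moved and 1 became weaker. Of 2105 alternative values of the other 290 results, 2021 stayed the same, 32 became weaker, 28 stronger, 23 moved and 1 reversed. The 23 that moved were values of named genes under total counts or another prior count. Size factors of DESeq2, both prior counts, robust dispersions, limma-voom, thinning and leaving out the genes near the targets or the immune genes moved no leading result. No paired analysis was possible because there was 1 library per genotype and the labels give no replicate numbers, and no library could be left out, since 1 residual degree of freedom was available. Depth limits genes of few counts, whose intervals are wide, and the spread between cultures of a genotype was not measured.

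The filters test different numbers of genes, which changes counts of genes by construction. Where ratios or shares moved, the cause was not tested. With CPM of at least 1 in at least 1 library, the double null against Trp53-/- had 168 genes higher and 220 lower (109 and 134 in the report). Zfp871 loss then had 72 genes in the same and 79 in opposite directions, and Trp53 loss 41 in opposite directions, with correlations for Trp53 of 0.756 (Pearson) and 0.652 (Spearman).

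With CPM of at least 10 in at least 2 libraries, higher and lower genes numbered 167 and 163 in Zfp871-/- against WT, 14 and 17 in the double null against Trp53-/-, 598 and 519 in Trp53-/- against WT, 291 and 337 in the double null against Zfp871-/-, and 594 and 546 in the double null against WT. Zfp871 loss had 6 genes in the same and 4 in opposite directions, with correlations of 0.05 and 0.121 (Pearson, Spearman). Trp53 loss had 510 and 2, with correlations of 0.824 and 0.698, and the edgeR test called 350 genes that rose and 357 that fell. The median of the zinc finger cluster in Zfp871-/- against WT reversed to -0.282. Of the genes near Zfp871, 0.0% were 2-fold different in either background.

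With no filter, the counts were 2198 and 2324 in Zfp871-/- against WT, 1001 and 1057 in the double null against Trp53-/-, 2546 and 3037 in Trp53-/- against WT, 1953 and 2534 in the double null against Zfp871-/-, and 2505 and 2973 in the double null against WT. Zfp871 loss had 327 genes in the same and 323 in opposite directions, with correlations of 0.005 and 0.02. Trp53 loss had 1911 and 275, with correlations of 0.518 and 0.377. The edgeR test called 2 genes that rose and 4 that fell with Zfp871 loss, and 1113 and 1191 with Trp53 loss. The Zfp871 calls were Rnf17 and Usp26 upward and Ltbp4, Hapln1, Col10a1 and C2cd4a downward. In WT, Zfp871-/-, Trp53-/- and the double null, Hapln1 had 404, 16, 2 and 0 counts. Col10a1 had 4863, 183, 16 and 7 counts and C2cd4a 195, 4, 3 and 0 in the same order. The calls of Hapln1, Col10a1 and C2cd4a thus rest mainly on Zfp871-/- against WT, with few counts in the Trp53-null pair. The p53 target difference between backgrounds was -0.137 and no longer stood apart from random lists; over all alternatives it ranged from -0.134 to -0.194, the latter without Cdkn1a and Mdm2. Near Zfp871, 15.0% of genes with Trp53 and 9.5% without it were 2-fold different, and near Trp53 24.2% in the double null against Zfp871-/-.

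DESeq2's Wald test called 3 genes upward and 5 downward with Zfp871 loss, where the edgeR test called 0 and 0. With total counts alone, the log2 ratio of Trp53 in the double null against Zfp871-/- was -0.963. With a window of 1 Mb, 0.0% of the genes near Zfp871 differed 2-fold in either background, and 12.5% of those near Trp53 in Trp53-/- against WT.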

Other observations

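Of these observations, mt-Nd3, Hoxd12 and the predicted gene Gm47283 were singled out only after their values were seen.

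Xist had 12139, 9152, 12564 and 14475 counts in WT, Zfp871-/-, Trp53-/- and the double null, and the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty together had 1, 0, 0 and 1. The predicted gene Gm47283, which the annotation places on the Y chromosome, had 154, 202, 337 and 0 counts in the same order.

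Among the mitochondrially encoded genes, mt-Nd3 had 34 and 38 counts in WT and Zfp871-/- and 309 and 359 in Trp53-/- and the double null. It rose by 2.95 on the log2 scale with Trp53 loss in the edgeR quasi-likelihood test (SE 0.234, Benjamini-Hochberg adjusted p 0.0148), while the median of the 12 measured genes of this list was -0.20 in Trp53-/- against WT.

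Hoxd12, which did not enter the tested genes, had 140 counts in WT, 13 in Zfp871-/- and 0 in both Trp53-null libraries. The list of other germline genes had 7 measured members, with median log2 ratios of 0.56 and -0.11 after Zfp871 loss with and without Trp53.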
